A study of Mus musculus with 80 samples.

How the data were processed

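Lung tissue of 72 mice and 8 aliquots labelled only as control RNA were measured on 80 Illumina MouseRef-8 v2.0 expression arrays, 1 array per sample. Per the labels' protocols, tissue was kept in RNAlater, total RNA was extracted with RNeasy Mini columns and had an integrity number of 7 or more, and all biological samples were amplified and labelled together with the TotalPrep-96 kit. Per the design text in the labels, samples were blinded and placed at random over the chips. The deposited values range from -4.29 to 15.8 and were taken as log2 expression made by the authors. The base of the logarithm, the scanner software, the background correction and the normalization between arrays are not given in the sources used here. The array quantiles differed slightly between arrays and were left as deposited, and no detection p was used. The 8 control RNA arrays carried chip numbers in their labels. The labels name no shared animal between lung arrays, and each was treated as 1 mouse.

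Arrays were grouped by the regimen and experiment time in their labels into 24 groups of 3 mice, LD and DD at 12 time points. Circadian time follows the labels, with experiment time 0 at CT 4. The probe annotation given with the series named 1 gene symbol for 23978 of 25697 probes, several for 0, and none for 1719, which were left unnamed. Entrez identifiers of 23962 of the named probes matched the gene table used here, and no symbol needed an update. A gene with several probes (4777 of 16593 genes) was represented by the probe with the highest mean over the 72 lung arrays. No filter on dim probes was set, since the level at which a probe is above background was not known, and differences of dim genes are less certain.

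Arrays whose Pearson correlation with the median profile of the 80 arrays was under 0.5 were treated as failed, a rule chosen after seeing the data, which removed 2 lung arrays. Every test was run on the 72 arrays and again on the remaining 70. Blocks of 8 consecutive columns of the deposited table were used as an assumed chip, since each of the 8 control arrays fell in the block of its own chip number.

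Tests were fitted across the 16593 genes on the log2 scale with limma 3.58.1 in R 4.3.3, with lmFit and eBayes (trend=TRUE), no weights and no block. For rhythms the model held, within each regimen, a mean, a linear term in experiment time, and the cosine and sine of a 24 h period (8 coefficients), with moderated F-tests of the LD terms, the DD terms and their difference. The amplitude is the log2 distance from mean to peak, and the fold from trough to peak comes from 2 amplitudes. Slopes are differences between the DD and LD linear terms in log2 per 24 h. Mean levels and the comparison at each time point came from a model with the 24 group means, as DD minus LD averaged over the 12 time points or at 1 of them. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. All tests except the list enrichment were two-sided. A peak within 4 h was the tolerance for shared timing, and 33.3% of unrelated peaks would meet it.

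The 36 gene lists fixed in advance held 624 different genes, of which 551 were measured. Clock lists were clock activators, clock repressors, and clock output and modifier genes. Metabolic lists were PPAR and fatty acid oxidation, FOXO with autophagy and atrophy, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, and hypoxia with glycolysis. Response lists were glucocorticoid-responsive genes, heat shock, cold-inducible RNA-binding proteins, the unfolded protein response, interferon-stimulated genes, inflammatory NF-kB targets, immediate early genes, and NRF2 and xenobiotic genes. Further lists held ribosomal proteins, the cell cycle, and fibroblast and matrix genes. Marker lists covered adipocytes, alveolar type 2 and type 1 cells, club, ciliated and endothelial cells, and smooth, cardiac and skeletal muscle. Blood lists covered B, T and NK cells, neutrophils, monocytes and macrophages, erythroid cells and platelets. Some genes stand in several lists. List members were counted among the genes called over all genes tested and again adjusted over the list alone. Levels and slopes of lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, and rhythms with a one-sided Fisher's exact test against the other genes, each adjusted over the 36 lists. Fisher's test treats genes as independent, which members of a list are not. Its p-values describe these lists rather than the spread between mice, and no estimated correlation was used for rhythms.

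The genes named were fixed by rule. The rule took all measured genes of the 3 clock lists, and the 10 largest amplitudes in LD and in DD among called genes whose peaks in the first and second cycle lay within 4 h. It took the 10 largest rises and 10 largest falls in level among called genes with the same sign at 10 or more time points, and the 5 largest rises and falls in slope. It also took the 10 largest called differences in rhythm, and up to 4 members per list with the largest effects. The rule was applied to the 70 arrays.

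The procedures were tested on simulated data drawn from the real means and spreads, with 200 of 16593 genes changed, 50 at each log2 size of 0.25, 0.5, 1 and 2. Noise was normal and independent between genes, without the shared variation of real arrays. The false calls given here may therefore understate those in the real data. With 70 arrays limma recovered 12, 19, 46 and 50 rhythms in LD, 4, 21, 45 and 50 in DD, and 5, 17, 40 and 49 differences in rhythm. It recovered 12, 30, 48 and 50 differences in level, 2, 7, 30 and 50 slopes, and 1, 1, 12 and 19 differences at 1 time point, with 1 to 6 false calls per comparison. With 72 arrays it recovered 0, 3, 33 and 50 rhythms in LD, 0, 6, 35 and 50 in DD, and 0, 1, 12 and 46 differences in rhythm. It recovered 0, 6, 44 and 50 differences in level, 0, 1, 10 and 41 slopes, and 0 differences of any size at 1 time point.

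The alternatives tried were quantile normalization, median centring, genes above the median level alone, the mean of all probes, eBayes without the trend, array weights, and the replicate number or the assumed chip as a block. For rhythms they were no linear term, an added 12 h harmonic, each cycle alone, circadian time as a factor of 6 levels, normal scores, each regimen fitted alone, and a 1.5-fold minimum from trough to peak. For levels and lists they were no time 0, the cosinor model for the level, an estimated correlation in camera. Each array was also left out in turn. The fits without the 28 h time point, the 44 h time point or both were chosen after seeing the data. Regrouped samples were drawn 100 times per count with a fixed seed. Control RNA arrays entered no comparison between regimens. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.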

Results

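Lung RNA was profiled across 2 daily cycles to ask which rhythms in gene expression persist when light and feeding cues are taken away. The 72 lung arrays came from 36 mice on a 12 h light and 12 h dark schedule with food throughout, called LD here, and 36 mice in constant darkness whose food was withdrawn when sampling began, called DD here. Lungs of 3 mice per regimen were collected at each of 12 time points from 0 to 44 h, 4 h apart, starting at circadian time (CT) 4, with CT 12 as the usual start of darkness. Darkness and fasting went together in DD and could not be separated. Another 8 arrays carried a control RNA of unstated origin. The number of arrays limits the precision, and values are on a scale taken as log2.

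Of the 72 lung arrays, 2 carried little lung signal. LD 32 h replicate 3 correlated with the median profile of the 80 arrays at r = 0.137 and DD 4 h replicate 1 at r = 0.149, where the other lung arrays reached 0.949 or more. Their values spread with an SD of 0.963 and 1.03 against 3.21 to 3.42 on the other arrays. Each comparison was fixed for all 72 arrays before the data were examined, and its count is given beside that from 70 arrays (35 LD, 35 DD), a fit chosen after seeing the data. Values of genes and gene lists come from the 70 arrays unless stated.

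The control RNA gave the technical spread. Over 16593 genes its median SD was 0.57 on the log2 scale across 8 arrays, against a median within-group SD of 0.66 among 70 lung arrays and 0.82 among 72. In the genes above the median level the control SD was 0.25 and the lung SD 0.33 with 70 arrays.

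Several clock genes had large daily rhythms in LD lungs. Arntl, which encodes the activator BMAL1, peaked at CT 23.2 with an amplitude of 2.62 ± 0.17 log2 (SE, 35 LD arrays, adjusted p = 2.3e-19), a 37.9-fold change from trough to peak. Genes driven by BMAL1 peaked on the other side of the day. Dbp, a PAR bZIP transcription factor, reached 3.02 ± 0.13 at CT 10.6 (adjusted p = 9.6e-30) and Nr1d1, the REV-ERB receptor that represses Arntl, 3.00 ± 0.15 at CT 8.34 (adjusted p = 6.1e-26). The period genes followed, with Per1 (1.26 ± 0.20, CT 11.5), Per3 (2.61 ± 0.17, CT 12.3) and Per2 at CT 14.4 (8.02-fold from trough to peak, SE of the amplitude 0.11). Nfil3 (1.05 ± 0.13, CT 22.8), a repressor of DBP targets, peaked close to Arntl.

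Of the clock activators measured, 4 of 5 were rhythmic in LD (4 adjusted over the list alone, Fisher's exact test over all lists, adjusted p = 3.5e-05), Arntl2 being the exception. Clock (0.55 ± 0.06, CT 23.4) and Npas2 (0.75 ± 0.19, CT 0.11) peaked with Arntl, and Rora peaked at CT 14.8 (0.33 ± 0.07). The rhythm of Npas2 was lost in 21 of the 70 fits that left out 1 array (highest adjusted p = 0.092) and without the 44 h time point (adjusted p = 0.096). Rora did not pass in either regimen with the mean of its probes (adjusted p = 0.70 in LD and 0.84 in DD). Of the clock repressors 7 of 11 passed (9 adjusted over the list alone, adjusted p = 6.6e-08), including Nr1d2 (2.31 ± 0.26, CT 11.1) and Bhlhe40 (0.46 ± 0.08, CT 11.9). Cry1, with an amplitude of 0.44 ± 0.25, Cry2 (0.61 ± 0.16), Ciart (0.49 ± 0.14) and Bhlhe41 (0.17 ± 0.16) did not. Of the clock output and modifier genes 4 of 11 passed (5 adjusted over the list alone, adjusted p = 6.8e-04). These were Dbp, Tef (1.12 ± 0.13, CT 12.5), Usp2 (1.19 ± 0.13, CT 12.9) and Alas1 (0.26 ± 0.06, CT 11.1), the first enzyme of haem synthesis. The rhythm of Alas1 was lost without LD 32 h replicate 2 or LD 32 h replicate 5 (highest adjusted p = 0.12), with median centring (0.063) and with the assumed chip as a block (0.051). Ciart was called with a 12 h harmonic added (adjusted p = 0.045) and without the 44 h time point (0.042). Hlf, Wee1, Nampt, Csnk1d, Csnk1e, Fbxl21 and Cdkn1a did not pass.

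Outside the clock lists, the largest LD amplitudes belonged to Spon2 (2.28 ± 0.18, CT 1.09), a secreted matrix protein, Fam124b (1.65 ± 0.19, CT 23.0), Avpr1a (1.61 ± 0.21, CT 23.0), a vasopressin receptor, and Msc (1.59 ± 0.14, CT 23.5), a bHLH transcription factor. Surfactant and alveolar type 2 cell genes had 5 of 16 rhythmic, with a mean peak at CT 4.50 (5 adjusted over the list alone, adjusted p = 3.1e-04), among them Cxcl15 (0.61 ± 0.06, CT 3.29) and Abca3 (0.31 ± 0.04, CT 3.75), the lamellar body lipid transporter. Fibroblast and matrix genes had 4 of 19 (5 adjusted over the list alone, adjusted p = 0.0045), led by Eln (1.04 ± 0.13, CT 2.35), elastin, and Loxl1 (0.50 ± 0.09, CT 4.17). Xenobiotic and NRF2 genes had 6 of 20 (6 adjusted over the list alone, adjusted p = 8.4e-05), led by Fmo2 (0.77 ± 0.11, CT 17.5) and Gsta3 (0.49 ± 0.05, CT 18.1). Glucocorticoid-responsive genes had 5 of 18 (9 adjusted over the list alone, adjusted p = 4.6e-04), with Errfi1 (0.64 ± 0.12, CT 9.12) and Tsc22d3 (0.56 ± 0.10, CT 14.6). Fatty acid synthesis genes had 4 of 18 (4 adjusted over the list alone, adjusted p = 0.0041), led by Dgat2 (1.27 ± 0.16, CT 10.8), the triglyceride-forming acyltransferase, and Scd1 (0.49 ± 0.08, CT 23.4). PPAR and fatty acid oxidation genes had 4 of 21 (5 adjusted over the list alone, adjusted p = 0.0055), with Acot1 (0.47 ± 0.09, CT 2.96). Heat shock genes had 4 of 17 (4 adjusted over the list alone, adjusted p = 0.0037), with Hspb1 (0.56 ± 0.12, CT 18.5). Immediate early genes had 4 of 21 (7 adjusted over the list alone, adjusted p = 0.0055), with Atf3 (0.87 ± 0.21, CT 9.35). The remaining 25 lists held 0 to 2 rhythmic members each, with adjusted p from 0.19 to 1.

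By limma's F-test 417 genes were rhythmic in LD with 70 arrays and 65 with all 72, of which 64 were shared, and 2417 passed at an unadjusted p under 0.05 with 70 arrays. Without the 28 h time point the count was 215, and the PPAR (adjusted p = 0.11), immediate early (0.58) and heat shock (1) lists were not called. The PPAR list was also lost with normal scores (adjusted p = 0.090) and in the first (1) and second (0.32) cycle alone. The heat shock list was lost without LD 28 h replicate 2, LD 28 h replicate 3 or LD 16 h replicate 1 (highest adjusted p = 1). It was also lost with circadian time as a factor (adjusted p = 0.072), each regimen fitted alone (0.17), array weights (0.67), normal scores (1) and the first cycle alone (1). The immediate early list was lost without LD 28 h replicate 3 (adjusted p = 0.68), with quantile normalization (0.052), normal scores (0.54) or no linear term (0.66), and in the first (1) and second (0.32) cycle alone. The fibroblast list was lost among genes above the median level (adjusted p = 0.067) and in the second cycle alone (0.32), and the glucocorticoid list in the first cycle alone (0.36). Hspb1 was not called without LD 28 h replicate 2 (adjusted p = 0.065), nor Atf3 without LD 28 h replicate 3 (adjusted p = 0.066). Neither was called without the 28 h time point (adjusted p = 0.088 and 0.23). Atf3 was also lost with no linear term (adjusted p = 0.061). Abca3 missed the threshold with the mean of its probes (adjusted p = 0.074). Of the genes named so far, the LD rhythms of Acot1, Alas1, Atf3, Bhlhe40, Errfi1, Hspb1, Loxl1, Npas2, Rora and Tsc22d3 were lost in at least 1 cycle alone (adjusted p from 0.053 to 0.44).

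Some lists not called in LD were called in other fits. The hypoxia list was called in 12 of the 70 fits that left out 1 array (lowest adjusted p = 0.017), with array weights (0.023) and with a 12 h harmonic added (0.021). The cold-inducible list was called without LD 40 h replicate 1, LD 44 h replicate 4 (lowest adjusted p = 0.0049) or the 44 h time point (0.0045). The cholesterol list was called without DD 36 h replicate 3 (adjusted p = 0.027) and with each regimen fitted alone (0.028), and the endothelial list in the first cycle alone (0.018).

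**Figure D1:**
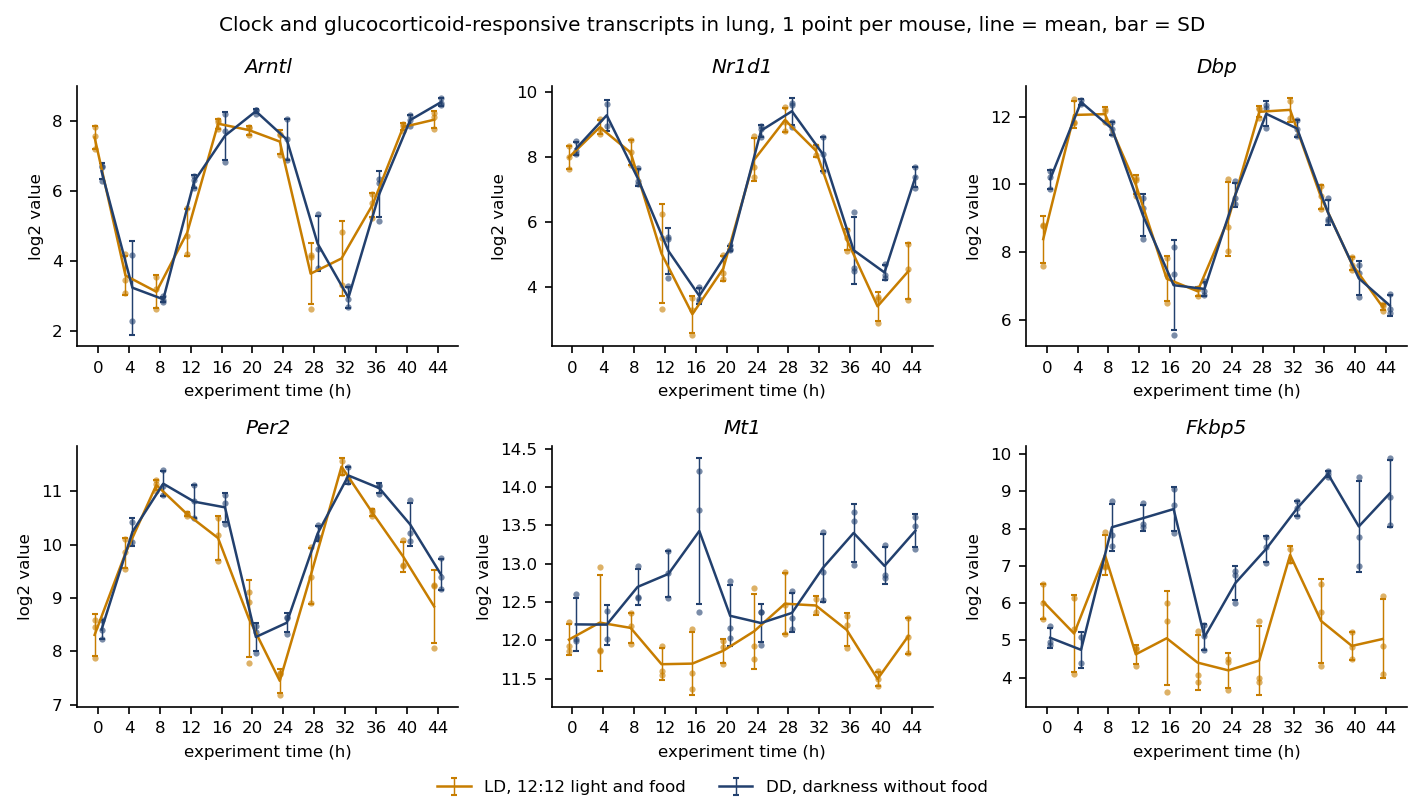
Log2 expression of Arntl, Nr1d1, Dbp, Per2, Mt1 and Fkbp5 against experiment time in hours, with a point per mouse, lines through the group means and bars of 1 SD for LD and DD with 70 arrays. The 4 clock genes peak at similar times in DD, while Fkbp5 lies higher in DD and Mt1 peaks at a different time.

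Clock genes were rhythmic in DD lungs too, and none of them passed the test for a different rhythm between regimens over all genes tested. Arntl peaked at CT 22.9 with an amplitude of 2.70 ± 0.17 (SE, 35 DD arrays, adjusted p = 1.4e-20), Nr1d1 at CT 7.23 with 2.86 ± 0.15 (adjusted p = 5.7e-25) and Dbp at CT 9.67 with 2.84 ± 0.13 (adjusted p = 2.5e-28). Per3 (2.34 ± 0.16, CT 11.9), Nr1d2 (2.08 ± 0.25, CT 10.04), Per2 (1.39 ± 0.11, CT 14.1), Nfil3 (1.34 ± 0.13, CT 21.0) and Per1 (0.90 ± 0.19, CT 11.9) also passed. Among other genes Spon2 (2.49 ± 0.18, CT 1.38) was again the largest. The B cell genes Blk (1.68 ± 0.27, CT 4.91), Cd79a (1.68 ± 0.23, CT 4.15) and Ly6d (1.67 ± 0.25, CT 4.91) joined the 10 largest amplitudes with Fam107a (1.58 ± 0.26, CT 15.4), an actin-associated protein.

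Of the clock lists, 4 of 5 activators (4 adjusted over the list alone, Fisher's exact test, adjusted p = 3.6e-04), 9 of 11 repressors (9 adjusted over the list alone, adjusted p = 6.6e-09) and 5 of 11 output and modifier genes (6 adjusted over the list alone, adjusted p = 8.1e-04) were rhythmic in DD. Ciart (0.71 ± 0.13, CT 12.1) and Cry2 (0.58 ± 0.16, CT 13.8) passed here, as did Cdkn1a (0.92 ± 0.14, CT 19.96), the cell cycle inhibitor p21. Cry2 was lost in 17 of the 70 fits that left out 1 array (highest adjusted p = 0.11), with the mean of all probes (0.053) and without the trend in eBayes (0.060). In LD it missed the threshold (adjusted p = 0.054) but was called in 9 of those fits and in 5 alternatives, including quantile normalization (adjusted p = 0.013) and array weights (0.0056). Clock (0.45 ± 0.06, CT 22.2), Npas2 (0.92 ± 0.19, CT 23.4), Rora (0.30 ± 0.07, CT 17.0), Bhlhe40 (0.41 ± 0.08, CT 10.7), Tef (1.07 ± 0.12, CT 12.1), Usp2 (1.04 ± 0.13, CT 13.3) and Alas1 (0.32 ± 0.06, CT 12.8) passed in both regimens, and Cry1 in neither (DD amplitude 0.55 ± 0.24).

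B cell markers formed the list with the most rhythmic members in DD outside the clock in proportion to its size, apart from the 3 cold-inducible genes. Of 12 measured, 8 passed (9 adjusted over the list alone, adjusted p = 5.1e-07), including Cd79b (1.25 ± 0.15, CT 4.57) and H2-Ob (1.17 ± 0.14, CT 4.75). NK cell markers had 3 of 10 (3 adjusted over the list alone, adjusted p = 0.042), with Nkg7 (0.61 ± 0.15, CT 5.41), and T cell markers 3 of 12 (4 adjusted over the list alone, adjusted p = 0.066). The T cell list was called with array weights (adjusted p = 0.021), a minimum of 1.5-fold (0.021), no linear term (0.028), genes above the median level (0.029), the second cycle alone (4.5e-04) and no 44 h time point (0.049). It was also called without DD 0 h replicate 3, DD 4 h replicate 3, DD 12 h replicate 3, DD 36 h replicate 3, LD 36 h replicate 5 or LD 44 h replicate 4 (lowest adjusted p = 2.4e-04). The NK list was lost without DD 36 h replicate 1, DD 12 h replicate 1, DD 12 h replicate 3 or LD 28 h replicate 2 (highest adjusted p = 0.23). It was also lost with quantile normalization (adjusted p = 0.065), array weights (0.076), no linear term (0.079) and the assumed chip as a block (0.27). With normal scores, circadian time as a factor, the first cycle alone or no 28 h time point its adjusted p was 1. Cold-inducible RNA-binding genes had 3 of 3 (3 adjusted over the list alone, adjusted p = 8.1e-04), Cirbp (1.06 ± 0.15, CT 5.31), Rbm3 (0.61 ± 0.11, CT 8.80) and Srsf5 (0.24 ± 0.06, CT 3.54). Heat shock genes had 5 of 17 rhythmic, with a mean peak at CT 17.8 (9 adjusted over the list alone, adjusted p = 0.0065), led by Hsph1 (0.91 ± 0.17, CT 18.0). Glucocorticoid-responsive genes had 8 of 18 (15 adjusted over the list alone, adjusted p = 2.2e-05), led by Fkbp5 (1.35 ± 0.23, CT 15.5), a co-chaperone of the glucocorticoid receptor, and Map3k6 (0.78 ± 0.18, CT 15.2). NRF2 and xenobiotic genes had 7 of 20 (9 adjusted over the list alone, adjusted p = 3.9e-04), with Cyp2b10 (0.48 ± 0.07, CT 15.8). Type 2 cell genes had 5 of 16 (7 adjusted over the list alone, adjusted p = 0.0054), with Cxcl15 (0.48 ± 0.06, CT 2.37). Fibroblast and matrix genes had 5 of 19 (7 adjusted over the list alone, adjusted p = 0.010), with Eln (0.79 ± 0.13, CT 0.89). Fatty acid synthesis genes had 4 of 18 (5 adjusted over the list alone, adjusted p = 0.042), with Dgat2 (1.10 ± 0.16, CT 10.3). The remaining 24 lists held 0 to 3 rhythmic members each, with adjusted p from 0.066 to 1.

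Limma's F-test called 894 genes rhythmic in DD with 70 arrays and 106 with all 72, each of which was also called with 70. The fibroblast list was lost without DD 40 h replicate 3 (adjusted p = 0.054), with array weights (0.087), in the second cycle alone (0.094), among genes above the median level (0.18) and with normal scores (0.62). The fatty acid synthesis list was lost without DD 12 h replicate 3 or LD 28 h replicate 2 (highest adjusted p = 0.054), with array weights (0.078), in the second cycle alone (0.30) and among genes above the median level (0.31). The heat shock list was lost among genes above the median level (adjusted p = 0.12) and in the first cycle alone (0.68), as was the cold-inducible list in the latter (0.23). The NRF2 list was lost with normal scores (adjusted p = 0.12) and the type 2 list with a minimum of 1.5-fold (0.28). The oxidative phosphorylation list, not called otherwise, was called with the assumed chip as a block (adjusted p = 0.012) and no linear term (0.034).

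Some genes named so far for a DD rhythm were lost in 1 cycle alone. In the first cycle these were Blk, Ciart, Cirbp, Cry2, Hsph1, Nkg7, Npas2 and Srsf5 (adjusted p from 0.099 to 0.86). In the second they were Alas1, Bhlhe40, Cry2, Eln, Fam107a, Fkbp5, Map3k6, Per1 and Rora (adjusted p from 0.051 to 0.55). Srsf5 was also lost without DD 12 h replicate 3 (adjusted p = 0.050), without the 44 h time point (0.053) or with no linear term (0.077), Nkg7 (0.093) and Rora (0.089) without the 28 h time point, and Rbm3 with the mean of its probes (0.27).

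Most rhythms shared by both regimens peaked at similar times, within the tolerance of 4 h. Both tests called 207 genes, against 22.5 for independent lists, and 203 of them (98.1%) peaked within 4 h of each other in LD and DD. The median DD peak lay at -0.27 h relative to the LD peak and the median amplitude was 0.39 in either regimen. Equal phase was not tested. Adjusted over the list alone, 2 of 11 clock repressors and 2 of 11 output and modifier genes passed for a different rhythm. Of 687 genes called in DD but not LD, 71.2% had fitted peaks within 4 h, as had 73.8% of the 210 genes called in LD but not DD, against 33.3% by chance and 37.3% of genes called in neither.

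**Figure D2:**
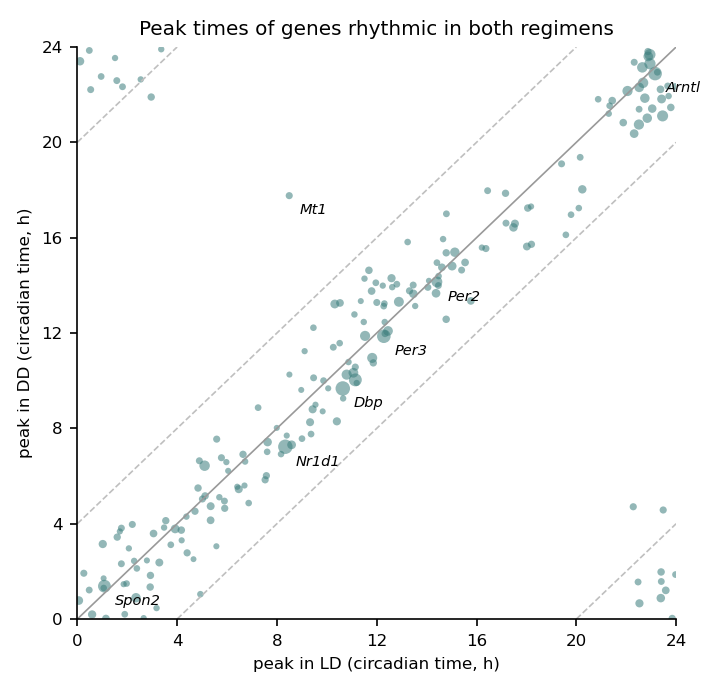
Peak circadian time in DD against peak circadian time in LD, in hours, for the 207 genes rhythmic in both regimens with 70 arrays. The dashed lines mark a gap of 4 h, and 203 genes lie between them.

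With 70 arrays limma called a difference in rhythm between regimens for 1 gene, Mt1. Mt1, a metal-binding metallothionein induced by glucocorticoids, peaked at CT 8.49 in LD (amplitude 0.40 ± 0.09) and at CT 17.8 in DD (amplitude 0.45 ± 0.09), 9.27 h later, and the difference vector measured 0.80 ± 0.13 (SE, 35 arrays per regimen, adjusted p = 0.0060). Its mean level was also higher in DD, by 0.72 ± 0.08. Glucocorticoid-responsive genes were the list called for different rhythms (Fisher's exact test, adjusted p = 0.039), on Mt1 alone of 18 members (3 adjusted over the list alone). With 1 gene called, this p rests only on the size of the list and on Mt1 being in it. It therefore says nothing about the other members. That list call was lost in 12 of the 70 fits that left out 1 array (highest adjusted p = 0.12). It was also lost in 10 alternatives (adjusted p from 0.074 to 1), among them genes above the median level, array weights, the assumed chip as a block, no linear term, normal scores and the fits without 28 h or 44 h. The other 35 lists had no member called over all genes tested, although 7 of 12 B cell markers passed adjusted over the list alone, and 0 to 3 members of each of the rest. Without DD 0 h replicate 3 the B cell list was called (adjusted p = 2.6e-04). In the first cycle alone the clock output list was called (adjusted p = 0.048). Limma called 1 gene with 70 arrays and 0 with all 72, where 1490 and 652 genes passed at an unadjusted p under 0.05. Mt1 was no longer called with the assumed chip as a block (adjusted p = 0.080), in the first cycle alone (0.14), or without the 28 h time point (0.13). With circadian time as a factor and with normal scores limma called 0 genes, so Mt1 was lost there too, where 966 and 1272 genes passed at an unadjusted p under 0.05. The LD rhythm of Mt1 was lost without the 28 h time point (adjusted p = 0.15) or LD 28 h replicate 2 (0.092), with the assumed chip as a block (0.069) or no linear term (0.084), and in the first (0.53) and second (0.15) cycle alone. With all 72 arrays the LD peak of Mt1 lay earlier and counted as reversed, as given below. Other settings called more genes, 8 in the second cycle alone, 7 with array weights, 4 in the first cycle alone or with no linear term, and 3 without the 44 h time point. Leaving out 1 array moved the count in 12 of 70 fits, to 6 without DD 0 h replicate 3, 3 without DD 44 h replicate 3 and 2 in the rest.

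Averaged over the 12 time points, DD lungs held more mRNA of genes that respond to fasting and glucocorticoids. Fkbp5 was higher by 2.06 ± 0.16 log2 (SE, 35 arrays per regimen, adjusted p = 5.1e-15), 4.18-fold, and higher at 10 of 12 time points. Pdk4, the kinase that shuts off pyruvate dehydrogenase, was higher by 1.87 ± 0.16 (adjusted p = 3.7e-13, 10 of 12) and Angptl4, an inhibitor of lipoprotein lipase, by 1.76 ± 0.12 (adjusted p = 2.2e-17, 10 of 12). The haemoglobin scavenger receptor gene Cd163 was higher by 1.65 ± 0.17 (adjusted p = 9.4e-11, 11 of 12). Lower in DD were Tbxa2r, the thromboxane receptor (-1.34 ± 0.15, adjusted p = 1.1e-09, 10 of 12), the growth factor Igf1 (-1.13 ± 0.20, adjusted p = 2.5e-05, 11 of 12) and Hspa1a, an inducible HSP70 (-1.21 ± 0.24, adjusted p = 1.5e-04, 10 of 12).

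The 10 largest rises with the same sign at 10 or more time points also held Fam107a (2.37 ± 0.20), Tcf23 (2.23 ± 0.23), Myrip (1.68 ± 0.11), Tent5b (1.61 ± 0.14), a poly(A) polymerase, Rbfox3 (1.48 ± 0.13), a splicing factor, and Map3k6 (2.83-fold, SE 0.12 log2). The 10 largest falls also held Wnt10b (-1.56 ± 0.31), Slco4a1 (-1.43 ± 0.30), Slc7a10 (-1.29 ± 0.17), an amino acid transporter, Gbp5 (-1.25 ± 0.22), an interferon-induced GTPase, Scn3b (-1.23 ± 0.12), a sodium channel subunit, Rbp7 (-1.12 ± 0.22) and Actc1 (-1.12 ± 0.26), cardiac actin. Tcf23, Wnt10b and Slco4a1 had low mean values, and Slco4a1 was not called with the mean of its probes (adjusted p = 0.097). Actc1 is one of the cardiac markers, whose mean varied widely between mice, as given below.

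Of the glucocorticoid-responsive genes 14 of 18 were higher and 0 lower in DD (15 adjusted over the list alone, camera adjusted p = 4.1e-31, adjusted p = 2.8e-05 with an estimated correlation). PPAR and fatty acid oxidation genes had 10 of 21 higher and 0 lower (11 adjusted over the list alone, adjusted p = 4.0e-12 and adjusted p = 3.7e-04 with an estimated correlation), including Acot1 (1.08 ± 0.06), an acyl-CoA thioesterase. FOXO, autophagy and atrophy genes had 11 of 21 higher and 0 lower (11 adjusted over the list alone, adjusted p = 8.2e-12 and adjusted p = 6.5e-04 with an estimated correlation), with Pik3ip1 (1.05 ± 0.12), Ddit4 (1.01 ± 0.13), an mTORC1 inhibitor, and Fbxo32 (0.86 ± 0.09), the ubiquitin ligase atrogin-1. Adipocyte markers had 4 of 14 higher and 0 lower (4 adjusted over the list alone, adjusted p = 0.011, but adjusted p = 0.38 with an estimated correlation), with Cidec (0.97 ± 0.20) and Pnpla2 (0.68 ± 0.06). They were no longer called without DD 4 h replicate 2 (adjusted p = 0.059). Clock repressors had 4 of 11 higher and 0 lower (4 adjusted over the list alone, adjusted p = 0.0017 and adjusted p = 0.049 with an estimated correlation), Per1 (0.92 ± 0.13), Cry2 (0.71 ± 0.16), Nr1d1 (0.48 ± 0.13) and Per2 (0.36 ± 0.08). Clock output and modifier genes had 6 of 11 higher and 0 lower (7 adjusted over the list alone, adjusted p = 3.7e-05 and adjusted p = 0.0045 with an estimated correlation), led by Cdkn1a (1.04 ± 0.10) and Usp2 (0.60 ± 0.11). Some of these genes also stand in the glucocorticoid-responsive list, so the lists are not independent. They are Cdkn1a, Per1 of the clock repressors, Pdk4 of the PPAR list, and Ddit4 and Sesn1 of the FOXO list. Clock activators had 1 of 5 higher and 0 lower (1 adjusted over the list alone, adjusted p = 0.16), the higher gene being Rora (0.33 ± 0.07), which was not called with the mean of its probes (0.21, adjusted p = 0.32). The 3 cold-inducible genes were each higher (3 adjusted over the list alone, adjusted p = 8.1e-06 and adjusted p = 0.0024 with an estimated correlation), Cirbp (0.77 ± 0.11), Rbm3 (0.46 ± 0.10) and Srsf5 (0.30 ± 0.06), and Rbm3 measured -0.08 with the mean of its probes.

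Cholesterol synthesis genes fell in DD, with 1 of 18 higher and 11 lower (13 adjusted over the list alone, adjusted p = 8.5e-11 and adjusted p = 0.0051 with an estimated correlation), including Dhcr7 (-0.95 ± 0.16), Cyp51 (-0.69 ± 0.12) and Mvd (-0.65 ± 0.10). Pmvk (0.82 ± 0.13) went the other way. Heat shock genes had 0 of 17 higher and 9 lower (10 adjusted over the list alone, adjusted p = 4.2e-09 and adjusted p = 0.023 with an estimated correlation), including Hsph1 (-0.61 ± 0.12) and Stip1 (-0.38 ± 0.05). Genes of the unfolded protein response had 1 of 19 higher and 8 lower (10 adjusted over the list alone, adjusted p = 2.6e-04 and adjusted p = 0.039 with an estimated correlation), with Pdia6 (-0.60 ± 0.11) and Hyou1 (-0.58 ± 0.17). Interferon-stimulated genes had 0 of 23 higher and 6 lower (9 adjusted over the list alone, adjusted p = 1.7e-05 and adjusted p = 0.035 with an estimated correlation), with Isg15 (-0.66 ± 0.11) and Gbp2 (-0.46 ± 0.08). Cell cycle genes had 0 of 35 higher and 4 lower (7 adjusted over the list alone, adjusted p = 0.0013, but adjusted p = 0.39 with an estimated correlation), with Mcm2 (-0.56 ± 0.10).

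Some muscle markers were lower in DD. Smooth muscle had 0 of 8 higher and 3 lower (5 adjusted over the list alone, adjusted p = 9.1e-04, but adjusted p = 0.21 with an estimated correlation), including Tagln (-0.95 ± 0.16). Cardiac muscle had 0 of 14 higher and 3 lower and a median of -0.89 (3 adjusted over the list alone, adjusted p = 0.0040, but adjusted p = 0.51 with an estimated correlation). The mean of the cardiac markers ranged from 2.08 (44 h replicate 2) to 9.12 (32 h replicate 3) among DD mice. Among LD mice it ranged from 2.36 (24 h replicate 2) to 8.77 (4 h replicate 5), so single mice weigh on this difference. Oxidative phosphorylation genes had 0 of 35 higher and 3 lower (3 adjusted over the list alone, adjusted p = 0.030, but adjusted p = 0.50 with an estimated correlation). Skeletal muscle markers had 0 of 11 higher and 0 lower (0 adjusted over the list alone, adjusted p = 0.63). Neutrophil markers had 0 of 13 higher and 0 lower and a median of 0.34 (0 adjusted over the list alone, adjusted p = 0.032, but adjusted p = 0.60 with an estimated correlation). Ribosomal protein genes had 4 of 29 higher and 0 lower (4 adjusted over the list alone, adjusted p = 0.0026, but adjusted p = 0.24 with an estimated correlation). NRF2 and xenobiotic genes had 5 of 20 higher and 1 lower (7 adjusted over the list alone, adjusted p = 4.2e-04, but adjusted p = 0.10 with an estimated correlation), with Cyp2b10 (0.56 ± 0.06) and Fmo2 (0.49 ± 0.10).

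The lists that were not called mostly held few changed genes. Fibroblast and matrix genes went both ways, 5 of 19 higher and 5 lower (12 adjusted over the list alone, adjusted p = 0.63), with the crosslinking enzyme Lox (1.11 ± 0.07) and Mfap4 (-0.46 ± 0.07) at the ends. Fatty acid synthesis genes also did, 2 of 18 higher and 6 lower (10 adjusted over the list alone, adjusted p = 0.16), with Dgat2 (0.56 ± 0.13) and Fads2 (-0.64 ± 0.11). Type 2 cell genes had 2 of 16 higher and 2 lower (5 adjusted over the list alone, adjusted p = 0.96), and monocyte and macrophage markers 2 of 11 higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.63). Immediate early genes had 1 of 21 higher and 2 lower (5 adjusted over the list alone, adjusted p = 0.96) and hypoxia and glycolysis genes 2 of 17 higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.67). NK cell markers had 0 of 10 higher and 2 lower (2 adjusted over the list alone, adjusted p = 0.20). Inflammatory NF-kB targets had 1 of 20 higher and 0 lower (1 adjusted over the list alone, adjusted p = 0.96), and type 1 cell markers 0 of 9 higher and 1 lower (1 adjusted over the list alone, adjusted p = 0.96). Endothelial markers had 0 of 14 higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.96) and erythroid markers 0 of 7 higher and 1 lower (1 adjusted over the list alone, adjusted p = 0.55). No member passed among club cell (adjusted p = 0.52), ciliated cell (0.45), B cell (0.96), T cell (0.63) and platelet markers (0.45), 0 also when adjusted over the list alone. Median, mean and camera's direction differed in sign for fatty acid synthesis, type 2, type 1, B cell, monocyte, NF-kB and immediate early genes, none of them called.

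Limma's test of the mean difference called 833 genes higher and 886 lower in DD with 70 arrays, against 134 and 125 with all 72, which were each called with 70 too. Camera called 18 lists with 70 arrays and 17 with 72, 16 of them in both, and 10 of the 18 held with an estimated correlation. The NK cell list was called with 72 arrays alone (adjusted p = 0.042), and the oxidative phosphorylation (0.59) and ribosomal (0.69) lists were not called there. Without the 28 h and 44 h time points, left out after seeing the data, 516 genes were higher and 475 lower. Without 44 h alone 493 were lower and Nr1d1 was not called (0.26, adjusted p = 0.31). Without both times Nr1d1 (0.26, adjusted p = 0.37) and Cry2 (0.46, adjusted p = 0.091) were not called, while the NK cell list was (adjusted p = 0.039). The adipocyte list was lost in that fit (adjusted p = 0.051). The fatty acid synthesis list was called without 28 h (adjusted p = 0.041) and without both times (0.026). The neutrophil list was lost in 17 of the 70 fits that left out 1 array and the oxidative phosphorylation list in 7 (highest adjusted p = 0.11 and 0.074). Without the 44 h time point neither was called (adjusted p = 0.47 and 0.12), nor was the neutrophil list without 28 h (adjusted p = 0.052) or 0 h (0.079), with the mean of all probes (0.087) or among genes above the median level (0.17). The oxidative phosphorylation list was also lost with median centring (adjusted p = 0.064) and above the median level (0.072), and the ribosomal list with quantile normalization (adjusted p = 0.16).

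**Figure D3:**
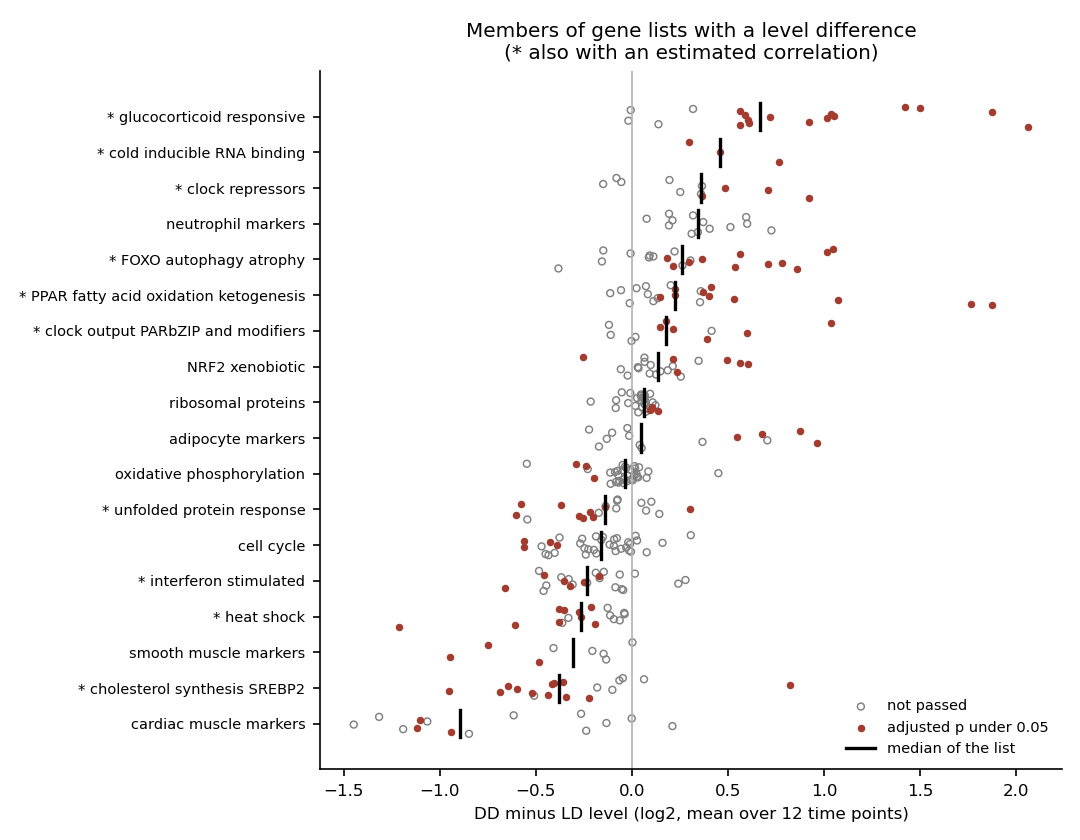
Log2 difference DD minus LD per gene, averaged over the 12 time points, for the 18 gene lists called by camera with 70 arrays, with a point per gene and a bar at each list's median. An asterisk marks the 10 lists also called with an estimated correlation.

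**Figure D4:**
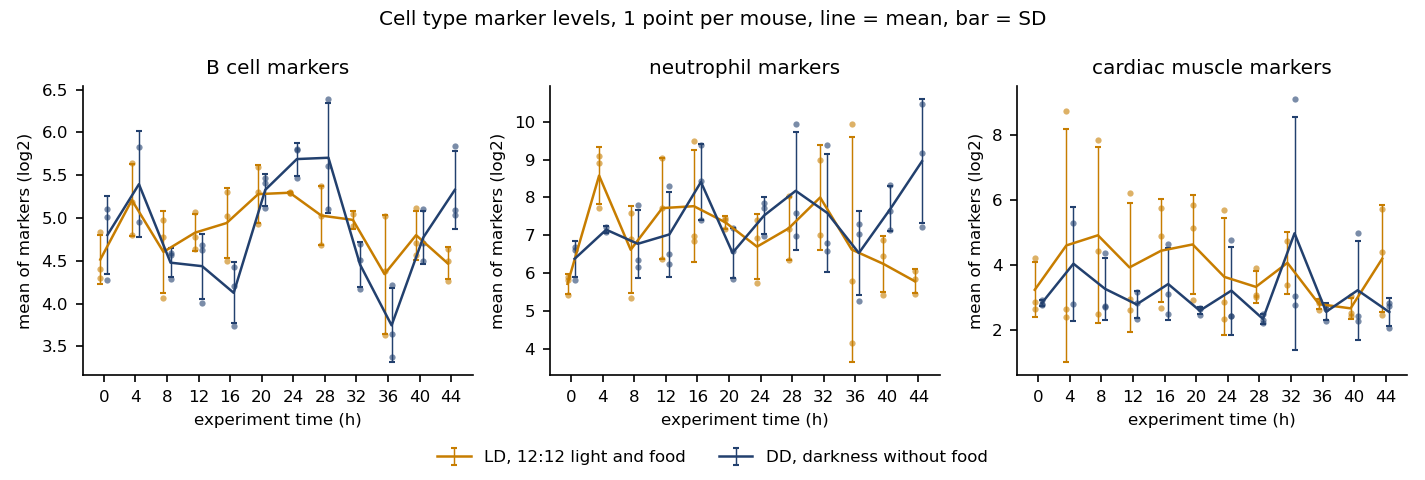
Mean log2 level of B cell, neutrophil and cardiac muscle markers per mouse against experiment time in hours, for LD and DD with 70 arrays, with a point per mouse, lines through the group means and bars of 1 SD. Single mice stand out for cardiac markers, and neutrophil markers at 44 h are higher in DD by 3.18 on average.

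Some differences grew as DD went on, and others turned downward. Scara5, a ferritin receptor, rose in DD relative to LD by 2.18 ± 0.44 log2 per 24 h (SE, 35 arrays per regimen, adjusted p = 0.0018), the lipid droplet gene Plin4 by 2.62 ± 0.61 (adjusted p = 0.0079) and Hspb7, a small heat shock protein of muscle, by 2.36 ± 0.52 (adjusted p = 0.0041). Scn3b changed by -2.11 ± 0.32 (adjusted p = 1.4e-04), Rnase1, a secreted ribonuclease, by -1.81 ± 0.40 (adjusted p = 0.0043) and Adamts1, a matrix protease, by -1.49 ± 0.29 (adjusted p = 0.0011). The 5 largest rises also held Tcf23 (2.38 ± 0.53) and Smoc1 (2.55 ± 0.76) and the 5 largest falls Gbp5 (-1.52 ± 0.41) and Fcrls (-1.41 ± 0.38). The falls of Gbp5 and Fcrls and the rises of Fkbp5 and Arrdc2 were lost without DD 44 h replicate 3, that of Arrdc2 also without DD 0 h replicate 2 (highest adjusted p = 0.067). The rise of Smoc1 was lost in 31 of the 70 fits that left out 1 array (highest adjusted p = 0.088).

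Glucocorticoid-responsive genes had 5 of 18 rising and 0 falling (9 adjusted over the list alone, camera adjusted p = 9.1e-07, but adjusted p = 0.40 with an estimated correlation), with Arrdc2 (1.97 ± 0.54), Map3k6 (1.65 ± 0.34), Pdk4 (1.64 ± 0.42) and Fkbp5 (1.62 ± 0.44). PPAR genes had 3 of 21 rising and 0 falling (8 adjusted over the list alone, adjusted p = 1.2e-04, but adjusted p = 0.18 with an estimated correlation), with Acot1 (0.85 ± 0.17). FOXO genes had 4 of 21 rising and 0 falling (6 adjusted over the list alone, adjusted p = 0.017, but adjusted p = 0.40 with an estimated correlation), with Txnip (0.61 ± 0.13). Of the adipocyte markers 3 of 14 rose and 0 fell (3 adjusted over the list alone, adjusted p = 0.0013, but adjusted p = 0.40 with an estimated correlation), with Plin4 and Lipe (1.54 ± 0.31). The mouse at DD 28 h replicate 1 had an adipocyte marker mean of 7.15 and DD 32 h replicate 3 came next at 5.64. Neutrophil markers had a median of 1.11 per 24 h and platelet markers 0.84, with no member called on its own or when adjusted over the list alone (adjusted p = 9.1e-04 and 0.0014, but adjusted p = 0.40 with an estimated correlation for either). Type 2 cell genes had 0 of 16 rising and 3 falling (7 adjusted over the list alone, adjusted p = 0.0042, but adjusted p = 0.40 with an estimated correlation), with Lamp3 (-0.59 ± 0.12), a lysosomal membrane protein. Fibroblast genes had 1 of 19 rising and 1 falling (5 adjusted over the list alone, adjusted p = 0.046, but adjusted p = 0.53 with an estimated correlation), with Lox (1.06 ± 0.17). Interferon-stimulated genes had 0 of 23 rising and 1 falling (3 adjusted over the list alone, adjusted p = 0.033, but adjusted p = 0.40 with an estimated correlation), with Gbp2 (-0.90 ± 0.16). Club and ciliated cell markers had no member called (1 and 2 adjusted over the list alone), with list tests at adjusted p = 0.025 and 0.0038, but adjusted p = 0.40 with an estimated correlation for either. The FOXO list was lost without DD 44 h replicate 3 (adjusted p = 0.063) and the club cell list without DD 32 h replicate 3 (adjusted p = 0.073). The fibroblast list was lost in 29 of 70 such fits and the interferon list in 12. Without the 44 h time point the neutrophil (adjusted p = 0.072), club cell (0.090), FOXO (0.14), interferon (0.18) and fibroblast (0.62) lists were lost. Without both 28 h and 44 h the platelet list was lost too (adjusted p = 0.11). With quantile normalization the type 2 list (adjusted p = 0.061) and the fibroblast list (0.17) were not called. Among genes above the median level the ciliated cell (adjusted p = 0.060), fibroblast (0.061), interferon (0.069) and club cell (0.19) lists missed the threshold. The chip block also ended the fibroblast call (adjusted p = 0.070). The other 25 lists had 0 or 1 member called and adjusted p from 0.063 to 0.93. Among these the median, mean and camera's direction differed in sign for clock activators, fatty acid synthesis, T cell, NF-kB and hypoxia genes.

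The list trends depended on the 2 failed arrays. With all 72 arrays camera called 13 lists, 8 of them also called with 70. The type 2 list had a median slope of 0.63 there (adjusted p = 0.054) against -0.11 with 70 arrays, and the fibroblast list 0.31 (adjusted p = 0.52) against -0.25, so both ran the other way. The interferon list was not called with 72 either (adjusted p = 0.54). Called with 72 arrays alone were clock repressors (adjusted p = 0.014), oxidative phosphorylation (0.014), endothelial (0.016), fatty acid synthesis (0.042) and ribosomal genes (0.043). With 70 arrays the cell cycle list was called in 20 of the fits that left out 1 array (lowest adjusted p = 0.0086) and in 5 alternatives, including the assumed chip as a block (0.0013) and quantile normalization (0.022). The clock repressors were called in 10 such fits (lowest adjusted p = 0.029) and oxidative phosphorylation genes in 6 (0.022). Clock output genes and heat shock genes were each called in 3, B cell markers in 2 and cold-inducible genes in 1. Without the 28 h time point lists called beyond the 11 were heat shock (adjusted p = 0.013), smooth muscle (0.013), cell cycle (0.013), cold-inducible (0.022), oxidative phosphorylation (0.022), cardiac muscle (0.032), immediate early (0.041) and unfolded protein response genes (0.047). Cardiac muscle was also called without 44 h (adjusted p = 0.039), and without both times cardiac and smooth muscle were (0.0023 for either). The assumed chip as a block added clock output (adjusted p = 0.011), smooth muscle (0.021), heat shock (0.022), endothelial (0.026) and clock repressor genes (0.043). The mean of all probes added clock output (adjusted p = 0.026), clock repressor (0.029), heat shock (0.029) and type 1 genes (0.038). The 12 h harmonic added clock repressor (adjusted p = 0.020), clock output (0.036) and cell cycle genes (0.044), and quantile normalization clock output genes (0.040).

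Among the genes named for a trend, Adamts1, Arrdc2, Fcrls, Fkbp5, Lipe, Pdk4 and Smoc1 were not called without the 28 h time point (adjusted p from 0.051 to 0.28). Arrdc2, Fcrls, Fkbp5, Gbp5, Map3k6, Pdk4, Plin4, Smoc1, Tcf23 and Txnip were not called without the 44 h time point (adjusted p from 0.054 to 0.33). With the mean of all probes Gbp2 (adjusted p = 0.30), Lipe (0.17) and Smoc1 (0.051) missed the threshold. Arrdc2 (adjusted p = 0.077), Gbp5 (0.061) and Smoc1 (0.060) did with array weights, and Fkbp5 (0.051) and Smoc1 (0.070) with the assumed chip as a block. By limma 278 genes rose and 279 fell in DD relative to LD with 70 arrays, against 38 and 8 with all 72, 46 of which were shared. With quantile normalization the 70 arrays gave 237 rises and 414 falls, a share of rises of 36.4% against 49.9%. The rises numbered 154 without DD 0 h replicate 2 and 156 without DD 44 h replicate 3, and the falls 169 without the latter. Limma called 0 of either without the 28 h and 44 h time points, where 1311 genes passed at an unadjusted p under 0.05. Within LD itself limma called 0 genes with a trend (1336 at an unadjusted p under 0.05). Within DD it called 535 rises and 484 falls.

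With 70 arrays the regimens differed in the most genes at 44 h (CT 0) and then at 28 h (CT 8). The place of 28 h depended on 1 LD array, as given below. At 44 h neutrophil markers had a median difference of 3.04 log2, platelet markers 2.17 and glucocorticoid-responsive genes 1.54, while cardiac muscle markers stood at -1.73, fibroblast and matrix genes at -0.88, interferon-stimulated genes at -0.71 and heat shock genes at -0.67. At 28 h adipocyte markers had a median of 1.33, glucocorticoid-responsive genes 1.04, platelet markers 0.99, neutrophil markers 0.89 and clock repressors 0.73, with cardiac markers at -1.18. The adipocyte and neutrophil values at 28 h rested largely on 1 mouse each. The adipocyte marker mean was 7.15 in DD 28 h replicate 1 and at most 3.34 in the other mice of either regimen at 28 h. The neutrophil marker mean was 9.94 in DD 28 h replicate 3. The other DD mice at 28 h had 6.99 and 7.59, within the LD range of 6.34 to 8.03. Glucocorticoid-responsive genes stood at -0.07 at 0 h, -0.30 at 4 h, 1.19 at 12 h and 1.35 at 16 h. These list medians were not tested per time point.

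With 70 arrays limma called 563 genes at 28 h (423 higher, 140 lower in DD) and 1243 at 44 h (439 higher, 804 lower), out of 2310 calls over the 12 time points, with 3 mice per group and 2 where an array had failed. At 0, 4 and 8 h no gene was called, with 971, 787 and 463 at an unadjusted p under 0.05, and the other time points gave between 6 at 20 h and 165 at 36 h. All 72 arrays gave 171 calls, 98 of them at 44 h. With the assumed chip as a block 157 genes were called at 28 h, 161 at 36 h and 1312 at 44 h, so the 28 h count then no longer exceeded that at 36 h. The 28 h count was 44 without LD 28 h replicate 2, 235 without DD 28 h replicate 1, 269 without DD 28 h replicate 3, 865 without LD 28 h replicate 5 and 1061 without LD 28 h replicate 3. LD 28 h replicate 2 had the lowest correlation with the median profile (r = 0.949) and the lowest SD (3.21) of the 70 lung arrays. It fell in the same assumed chip as other lung arrays with low correlations, as given below. Without LD 28 h replicate 2 the 28 h count lay below the 165 calls at 36 h. The 44 h count was 462 without DD 44 h replicate 3 and 790 without LD 44 h replicate 3.

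**Figure D5:**
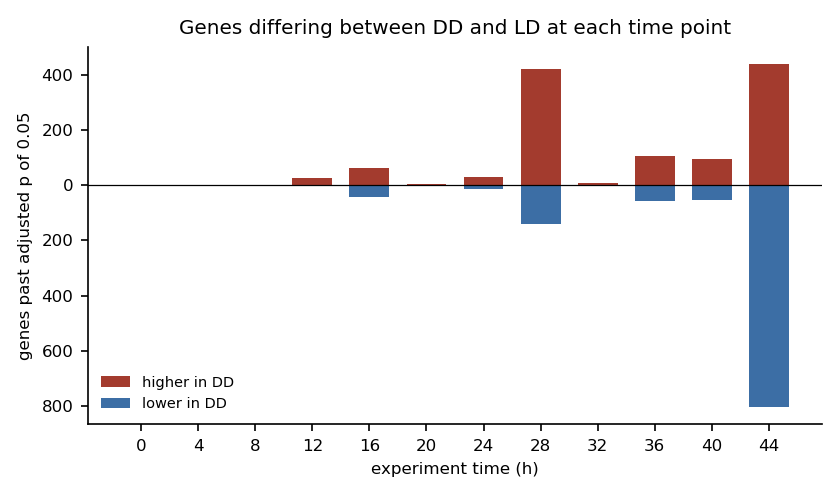
Number of genes called higher or lower in DD than LD at each experiment time in hours, with 70 arrays. The counts are 563 at 28 h and 1243 at 44 h, and 0 at 0, 4 and 8 h.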

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

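The tests of weak rhythms near the threshold and of retained blood were chosen only after the result was seen, as were the fits with 70 arrays.

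More genes were rhythmic in DD (894) than in LD (417) with 70 arrays, but normal scores gave 240 and 215. A larger spread in LD is argued against by the median LD to DD ratio of residual SD, 0.995. A candidate explanation is that many weak rhythms in both regimens lay near the adjusted threshold, since the DD to LD ratio was 1.16 among genes at an unadjusted p under 0.05, less the 830 counted by chance, and 2.14 after adjustment, although with all 72 arrays the unadjusted counts ran the other way (956 in DD, 1819 in LD). Chance could not be excluded either, because 5 of 100 relabellings of the regimen within time points, the real one included, gave a difference in counts as large as the real 477, the highest other being 691. An effect of darkness or fasting on the number of rhythms stays open and was not tested apart from the regimen.

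B cell markers were rhythmic in DD in 8 of 12 genes, and the mean of the 12 had an amplitude of 0.76 ± 0.12 (SE) at CT 4.68 in DD against 0.16 ± 0.11 at CT 4.45 in LD. The rhythm of this mean differed between regimens in a permutation test (p = 2.0e-05 over 100000 relabellings of the regimen within time points), which drew attention as a difference between groups, although limma called no B cell gene for a different rhythm over all genes tested, while 7 of 12 passed adjusted over the list alone. The B cell list was taken up for its rhythm in DD, which favours such a difference, and the permutation p was not adjusted for that choice. Array batch is argued against, since 8 markers stayed rhythmic with the assumed chip as a block. The amount of B cell RNA in the tissue may have varied over the day in DD. In DD 9 of 12 markers peaked within 4 h of the list mean, a count between the bounds set beforehand, which leaves this open. In LD 9 of 12 had a fitted peak within 4 h of CT 4.68, the DD peak of the mean. Regulation within B cells also stays open. The list shares 0 genes with the other lists, and NK and T cell means had DD amplitudes of 0.29 ± 0.08 and 0.31 ± 0.12.

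Neutrophil and platelet markers were higher in DD than LD at 44 h, by 3.18 log2 (95% interval 1.27 to 5.09, 3 mice per group) and 1.84 (0.42 to 3.26). Both lists had their largest median difference at 44 h, and the intervals were not adjusted for picking that time point. Neutrophil means at 44 h were 7.22, 9.17 and 10.5 in DD mice and 5.44 to 6.06 in LD mice. Single LD mice at other times reached 9.93 (36 h replicate 2) and 9.49 (16 h replicate 4). Chance variation between mice therefore stays open. For neutrophil markers, leaving out each of the 6 mice gave a lowest difference of 2.41, without DD 44 h replicate 3. This argues against a single mouse as the whole cause. Array batch is argued against by the neutrophil difference of 3.09 with the assumed chip as a block. The platelet difference was not tested in these ways. Red cell markers did not rise along, differing by -0.17 with an interval of -0.71 to 0.37. Their mean was not shown to follow the blood content of a lung, so more retained whole blood stays open. A rise of neutrophils and platelets in the lung with fasting or darkness is a hypothesis that stays open, and RNA changes within these cells could not be separated from it. The neutrophil list shares 1 gene with other lists and the platelet list 0.

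Other splits of the samples were counted 100 times each, the real one included, by shuffling time labels within a regimen for rhythms and regimen labels within time points for the rest. With 70 arrays only the real split reached the real count (1 of 100) for rhythms in LD (417, highest other 1), rhythms in DD (894, highest other 2), genes higher (833, highest other 128), lower (886, highest other 65), rising (278, highest other 57) and falling (279, highest other 28) in DD, and calls over the time points (2310, highest other 1106). With 100 splits, 1 of 100 is the lowest share possible. These shares argue against chance for the counts as a whole, but not for each gene in them. The 70 arrays were also chosen after seeing the data. With 72 arrays, too, only the real split reached the real count (1 of 100) for LD (65, highest other 0), DD (106, highest other 2), higher (134, highest other 0), lower (125, highest other 4), rising (38, highest other 1), falling (8, highest other 0) and calls over the time points (171, highest other 68). The single difference in rhythm with 70 arrays was reached in 3 of 100 splits (real 1, highest other 1), which is under the bound of 5. Shuffled regimens thus also gave 1 such gene, and a count over all genes does not test Mt1 itself. Chance was not excluded for it, the more so as the 70 arrays were chosen after seeing the data. With 72 arrays the real count was 0, which all 100 splits must reach (highest other 2), so they say nothing about chance.

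The Mt1 rhythm differed between regimens with limma's adjusted p = 0.0060. The DD minus LD difference changed over time in 278 rising and 279 falling genes, and so differed between time points. Among the 8 control RNA arrays, RNA control 9 stood apart from the others, with a gap of 0.596 of the range in the median absolute deviation from the control mean (0.368 against 0.248 to 0.296). The correlation of the control arrays with the median profile also had 1 extreme array, again RNA control 9 (0.857), with a gap of 0.557 of the range. Chance marks about 1 in 20 such groups. However, the lung arrays with the lowest such correlations among the 70 fell in the same assumed chip. They were LD 28 h replicate 2 (0.949), DD 0 h replicate 2 (0.966), DD 16 h replicate 3 (0.966), LD 36 h replicate 5 (0.966) and LD 32 h replicate 2 (0.969). A difference shared by that assumed chip therefore stays open. Of the 1719 probes left unnamed, which no comparison used, 23 were rhythmic in LD, 71 were rhythmic in DD, 72 were higher and 48 lower in DD, and 42 had a different slope, with limma and 70 arrays.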

How the results depend on the processing

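All fits with 70 arrays and those without the 28 h or 44 h time points were chosen after seeing the data, and the other alternatives before. With 72 arrays and with the 70 left without them, the counts were 65 and 417 rhythmic genes in LD, 106 and 894 in DD, 0 and 1 with a different rhythm, 134 and 833 higher and 125 and 886 lower in DD, 38 and 278 rising, 8 and 279 falling, and 171 and 2310 calls over the time points. The lists called for rhythms numbered 3 and 11 in LD, 3 and 12 in DD, and 0 and 1 for different rhythms. The median within-group SD exceeded that of the control RNA by 0.256 with 72 arrays and 0.0897 with 70, and above the median level by 0.522 and 0.0821.

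With 72 arrays, array weights gave 339 rhythmic genes in LD, 1011 in DD, 5 with a different rhythm, 923 higher, 983 lower, 170 rising and 156 falling. They also gave 2392 calls summed over the time points, and 11 LD and 10 DD lists. The first cycle alone gave 18 genes in LD, 44 in DD, and 1 gene and 1 list with a different rhythm, and the second cycle alone 1 LD list. Circadian time as a factor gave 31 and 58 rhythmic genes, and normal scores 157 in LD with 7 LD and 5 DD lists. Median centring gave 70 rhythmic genes in DD, 76 lower, 4 falling and 1 LD list, and moved the median slope of all genes from 0.09 to 0.21. Quantile normalization gave 6 rising and 5 falling, a share of rises of 54.5% against 82.6%, and 2989 calls summed over the time points. Without the trend in eBayes 20 genes rose, and above the median level 4 fell and 7 lists had a slope against 13. The chip block gave 21 slope lists, no linear term 5 DD lists, and an estimated correlation in camera 2 level lists against 17 and 0 slope lists.

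With 70 arrays, the first cycle alone gave 112 rhythmic genes in LD and 446 in DD, 4 with a different rhythm and 2 such lists, and the second cycle 128 in LD, 8 with a different rhythm and 0 such lists. Circadian time as a factor gave 227, 482 and 0 genes with 0 lists for different rhythms, and normal scores 215, 240 and 0 with 0 lists. Without the 28 h time point there were 215 rhythmic genes in LD, 0 with a different rhythm and 0 such lists, 51 rising, 93 falling and 18 slope lists. Without 44 h there were 3 genes and 0 lists with a different rhythm, 493 lower, 41 rising, 31 falling, 1071 calls summed over the time points and 7 slope lists. Without both there were 175 rhythmic genes in LD, 0 genes and 0 lists with a different rhythm, 516 higher, 475 lower, 0 rising and 0 falling. That fit also gave 613 calls summed over the time points and 7 slope lists. A minimum of 1.5-fold left 568 DD genes. Array weights gave 7 different rhythms in 0 lists and 184 rising, the chip block 0 in 0 lists and 172 falling, no linear term 4 in 0 lists, and genes above the median level 7 slope lists and 0 for different rhythms. Where limma called 0 different rhythms, 966 genes passed at an unadjusted p under 0.05 with the factor, 1272 with normal scores, 955 without 28 h, 775 without both times and 1255 with the chip block, as did 652 with all 72 arrays, and 1311 had a slope without both times. An estimated correlation left 10 of 18 level lists and 0 of 11 slope lists. The other alternatives moved these counts by 1.5 times or less. Fewer samples or genes entered the single cycles, the fits without time points and those above the median level. The cause was not tested for the others.

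The replicate number as a block gave 54 lower with 72 arrays, a share of higher calls of 67.3% against 51.7%, and 383 calls summed over the time points. With 70 arrays it gave 648 higher and 625 lower. There it ended the level calls of the cardiac muscle (adjusted p = 0.070) and neutrophil lists (0.065). It also ended the LD calls of the immediate early list (adjusted p = 0.15), Npas2 (0.13) and Atf3 (0.078), and added the cell cycle list for slope (0.038). The numbers did not pair the samples, since 21 pairs of deviations with the same number had a median r of 0.009, from -0.069 to 0.128, and 2 exceeded 0.1.

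Leaving out each array in turn gave, with 72 arrays, 43 to 197 rhythmic genes in LD, 83 to 168 in DD, 0 to 1 different rhythms, 112 to 303 higher, 101 to 300 lower, 13 to 53 rising, 2 to 12 falling and 102 to 7942 calls summed over the time points, with 15 to 18 level lists, 9 to 18 slope lists, 2 to 3 LD lists, 3 to 5 DD lists and 0 to 0 different. With 70 arrays the ranges were 278 to 465, 700 to 968, 1 to 6, 778 to 888, 800 to 940, 154 to 338, 169 to 394 and 1630 to 2844, with 16 to 18, 8 to 15, 9 to 12, 10 to 13 and 0 to 1 lists. Where 1 mouse was left in a group, it was assumed to vary like the other groups.

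Of 161 gene values in the text, 156 were called with 70 arrays, 82 of them also with 72, and 144 in every fit that left out 1 array, while 12 were lost in at least 1. Besides the results reversed below, calls were lost for 71 values with 72 arrays, 10 with the mean of all probes, 13 without 28 h, 13 without 44 h, 30 without both times, and 19 and 17 of 79 rhythms in the first and second cycle alone. Quantile normalization of the 70 arrays lost 0 of these limma calls and added 1. The reversed results were the LD peaks of Alas1 (amplitude 0.27, CT 23.0) and Mt1 (0.32, CT 2.41) and the slope of Lamp3 (0.069) with 72 arrays, and the level of Rbm3 with the mean of its probes (-0.076), and the cause was not tested. Background levels of single probes were not known, which limits dim genes. The alternative for linear intensities was not run, since the values were already logarithms.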

Other observations

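Observations here rest on 70 arrays, chosen after seeing the data, and no test was added for them. Single markers of resident and recruited cells differed in level although their lists were not called. Plac8, a monocyte marker, was lower in DD (-0.80 ± 0.13 log2, SE, 35 arrays per regimen, limma adjusted p = 5.1e-06), while the macrophage mannose receptor Mrc1 (0.38 ± 0.06) was higher. Lower in DD were also Aqp5 (-0.33 ± 0.05), the water channel of type 1 cells, Emcn (-0.26 ± 0.06), a sialomucin of capillary endothelium, and the immediate early gene Egr1 (-0.60 ± 0.13). The hexokinase gene Hk2 (0.42 ± 0.07) was higher and the vascular growth factor gene Vegfa (-0.20 ± 0.05) lower.

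Outside the lists described as rhythmic, Adm (1.28 ± 0.21, CT 22.1), which encodes the vasodilator adrenomedullin, was rhythmic in LD (adjusted p = 1.2e-04), though not in the second cycle alone (0.057), and it reached 1.16 ± 0.21 at CT 22.2 in DD (adjusted p = 2.4e-04). The T cell gene Cd8b1 (1.04 ± 0.15, CT 4.87) was rhythmic in DD (adjusted p = 3.7e-06), though not in the first cycle alone (0.13). The mean of the T cell markers had an amplitude of 0.26 ± 0.12 at CT 8.72 in LD and 0.31 ± 0.12 at CT 5.82 in DD, and that of the NK cell markers 0.07 ± 0.09 and 0.29 ± 0.08, the latter at CT 5.23. These means were not tested.

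Peak times had different distributions in the called genes, which was not tested. Of 417 genes rhythmic in LD, 117 peaked from CT 20 to 24, 69 from 0 to 4, 78 from 4 to 8, 69 from 8 to 12, 43 from 12 to 16 and 41 from 16 to 20. Of 894 genes rhythmic in DD, 267 peaked from CT 4 to 8, and the other bins held 115, 118, 161, 148 and 85, counted from CT 0. Of the 207 genes called in both, 93 had the larger amplitude in DD. Of the genes called for both level and slope, 335 had the same sign and 0 the opposite. Cardiac marker means varied widely between mice, with 9.12 at DD 32 h replicate 3 and 8.77 at LD 4 h replicate 5.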
